A study of Homo sapiens with 8 samples.

How the data were processed

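The series holds mRNA sequencing of Calu-6 cells, labelled as a wild-type lung line, in 8 libraries: DMSO or 1 µM KI696 for 24 or 48 h, 2 libraries per group. Cells were grown in 6-well plates. RNA was purified on silica columns with DNase digestion, poly(A) RNA was selected, and libraries were read on a NextSeq 500 as single reads of 75 bp, per the labels. The submitters name the hg38 genome build, R 4.0.3 and edgeR with no version. The aligner, the counting tool, the gene annotation, the strand setting and the gene filter are not given in the sources used here.

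The deposited table holds log2 values, taken here as log2 CPM (counts scaled to an effective library size) by the authors, with a small count added that scales with that size. This was read from the values: they reach below 0, share a floor of -2.05 (0.242 CPM) in all 8 columns, and on the antilog scale step in whole reads. Reads per gene and library were recovered from these steps, with a largest distance to a whole number of 2.4e-09 reads. The recovered reads sum to 6974235 to 14170211 per library, the 10 highest genes hold 3.95 to 4.64% of them, and 215 to 712 genes per library have no read. Reads outside the table are not known. Reads in the table came to 0.975 (DMSO 24 h B) to 1.04 (KI696 48 h B) of the effective size that the steps imply. They exceeded this size in DMSO 48 h B and in KI696 48 h A and B, so it was not a plain read total. The factor that had been applied is not given. A floor of 3 reads corresponds to 0.213 to 0.428 CPM per library. Between the 2 libraries of a group, chi-square per degree of freedom was 1.70 for DMSO 24 h, 4.88 for DMSO 48 h, 1.63 for KI696 24 h and 3.65 for KI696 48 h, where counting error alone gives about 1. Column headers name the condition and no replicate number, so libraries could not be paired across groups, and A and B follow column order.

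The table lists 14556 genes. In 21 of these the symbol had been turned into a calendar date by spreadsheet software, and they were left out because the gene cannot be told, which left 14535. Genes with at least 1 CPM in at least 2 of the 8 libraries were tested, 13213 in all. Symbols of 12242 of these (92.7%) matched GENCODE release 29, which gave the coordinates. Reads shared between close paralogs, such as AKR1C1, AKR1C2 and AKR1C3, cannot be separated here.

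Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with a mean per group, a variance trend, two-sided moderated tests and Benjamini-Hochberg adjustment over all tested genes at 0.05. The residual degrees of freedom were 4, and 13.1 with those lent by the other genes. The error of each gene was shared by all groups. The contrasts were KI696 against DMSO at 24 h and at 48 h, the difference between these effects, and DMSO at 48 h against 24 h. The plan written before the data were examined expected linear values and log2 of the value plus 1. Because the table already held log2 values, these were tested as deposited, and log2 of CPM plus 1 became an alternative chosen after seeing the data.

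Named genes follow a rule fixed before the data were examined. For each KI696 contrast these are the 10 largest increases and 10 largest decreases among called genes with a mean of at least 5 and with both treated libraries on the same side of both DMSO libraries. The mean was taken in CPM. For the other contrasts they are the 5 largest each way, without the overlap condition for the difference of effects. NFE2L2, KEAP1, NQO1, HMOX1, GCLM, GCLC, SLC7A11, TXNRD1, SRXN1 and ALDH3A1 were named in advance, and up to 4 members per described list come from the smallest p. Some genes that meet the rule are left out of the text. Levels are means of CPM with SD over 2 libraries.

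Before the data were examined, 33 gene lists with 816 entries were fixed, of which 763 are in the table. They cover NRF2 core targets, glutathione, thioredoxin, NADPH production, aldehyde and phase II enzymes, heme and iron, efflux transporters, KEAP1-NRF2 regulators, the proteasome, ATF4, the unfolded protein response, heat shock, glycolysis, hypoxia, complex I, the tricarboxylic acid cycle, cholesterol and fatty acids. They also cover DNA replication, mitosis, p53, interferon, NF-kB, immediate early, matrix, epithelial, lysosome, ribosomal and histone genes, and markers of leukocytes, of fibroblasts and endothelium, and of the lung lineage. The list of mitochondrially encoded mRNAs had 0 members in the table and was not tested, which left 32 lists of at least 5 tested members. Each was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 32 lists, then again with an estimated correlation. With an estimated correlation no list passed in any of the 4 contrasts. The fry test, which asks whether a list's genes move on balance in a single direction, was an alternative.

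The alternatives were pseudocounts of 0.25 and 5 CPM, no gene filter and a filter of 5 CPM, TMM, median-ratio and quantile scaling, no variance trend, each time point alone, a fold threshold, and each library left out in turn. Where a group was left with 1 library, its spread was taken from the other groups. Added after seeing the data were precision weights (limma's voom) on the recovered reads, the mean of the lung lineage list per library as a covariate, the libraries A of both 48 h groups left out, and the 247 genes that track the lung lineage pattern left out. The method was tested on simulated data with 13213 genes in the 24 h comparison. It called 20% of genes changed 1.25-fold, 72% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, each out of 50. Among its calls 13.8% were false in the first draw and 8.54% on average over 20 draws, above the nominal 5%. A comparison simulated without change, at 48 h, gave 0 calls. Each simulated gene had the same spread in all 8 libraries. In the data the 48 h pairs differed more than the 24 h pairs, so this does not give the rate of false calls at 48 h. The list test camera found a list with a simulated shift, and 4 of 100 unchanged lists. Genes varied independently in this simulation, so it cannot show the error rate for lists whose genes move together.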

Results

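Messenger RNA was sequenced from Calu-6 cells, a human non-small cell lung cancer line recorded with a wild-type genotype. The cells had been exposed for 24 or 48 h to 1 µM KI696, a small molecule that blocks the binding of KEAP1 to the transcription factor NRF2, or to its vehicle DMSO. The series held 8 libraries in 4 groups of 2. The comparisons asked how transcript levels changed with the compound at each time, whether that change differed between the times, and how the vehicle cultures drifted. Libraries of a group are called A and B by the order of their columns, to which the headers give no other meaning. The DMSO libraries held 8265115 (24 h, A), 7048197 (24 h, B), 7129593 (48 h, A) and 14170211 (48 h, B) reads, and the KI696 libraries 8161520, 6974235, 7273973 and 10738749 in the same order. A limit of 3 reads corresponded to 0.213 to 0.428 CPM (counts scaled to effective library size), and it covers counting error only. Nothing in the labels says whether the libraries of a group came from separate cultures, so the p-values may cover only technical spread.

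Treatment was the strongest separation between libraries, and NRF2 target genes lay higher in each KI696 library than in each DMSO library. Averaged over the NRF2 core list, the DMSO libraries lay between 4.68 and 5.02 log2 CPM and the KI696 libraries between 6.72 and 6.75. The first principal component held 61.1% of the variance. It placed the DMSO libraries between -41.4 and -31.5 and the KI696 libraries at 50.4, 47.9, 7.92 and 40.3, the third of these being library A of 48 h. A second pattern crossed the groups. Lung lineage genes averaged 3.11 and 3.35 log2 CPM in the DMSO libraries of 24 h, and 1.79 (A) and 0.49 (B) in those of 48 h. They averaged 0.36 and 0.50 in the KI696 libraries of 24 h, and 2.58 (A) and -0.24 (B) in those of 48 h. Epithelial genes also lay higher in library A than in library B at 48 h, at 5.04 and 3.90 in DMSO and 4.80 and 2.93 in KI696. Over all tested genes, the difference between libraries A and B had a correlation of 0.48 between the 48 h groups. In all, 247 genes were higher by 1 log2 unit or more in library A than in library B of both 48 h groups, and 3 were lower by as much in both. Of these 247 genes, 213 were called lower at 24 h and 0 higher, with a median change of -2.84, and 5 were called lower at 48 h and 0 higher, with a median of -0.43. The genes were chosen for a difference within both 48 h groups, which by itself works against calls at 48 h.

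**Figure D1:**
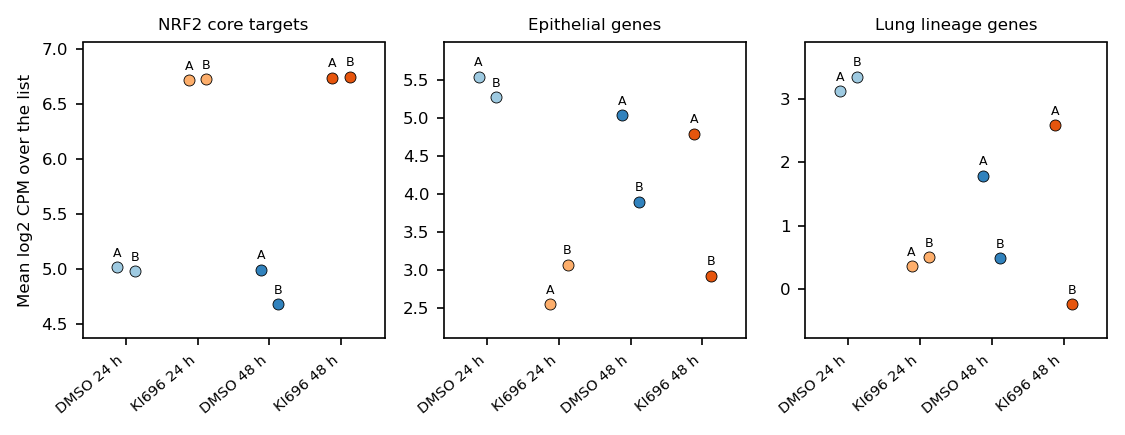
Mean log2 CPM of the NRF2 core, epithelial and lung lineage gene lists in each of the 8 libraries, grouped by treatment and time. NRF2 core targets lay at 6.72 to 6.75 in the KI696 libraries and at 4.68 to 5.02 in the DMSO libraries, while lung lineage genes differed between the 2 libraries of each 48 h group.

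After 24 h of KI696, several of the steepest increases were in genes of the antioxidant and detoxification response driven by NRF2. AKR1C2 (chromosome 10, 4987400 to 5018031 in hg38), an aldo-keto reductase of steroid and carbonyl metabolism, rose from 3.87 ± 0.600 to 124 ± 4.92 CPM (mean ± SD, n = 2 libraries per group, here and below), a log2 change of 4.92 (SE 0.39) with adjusted p = 1.0e-06. The other 9 of the 10 largest increases ranged from 2.60 to 4.69. They were the aldo-keto reductases AKR1B10 at 3.89 (SE 0.42), AKR1C1 at 3.10 (SE 0.17) and AKR1C3 at 2.75 (SE 0.11), the aldehyde dehydrogenase ALDH3A1 (from 3.55 ± 0.656 to 44.7 ± 0.0582 CPM), OSGIN1, the sulfiredoxin gene SRXN1, the thrombin receptor family gene F2RL2, TRIM54 and LOC344887. LOC344887 rested on 11 reads in the DMSO group, and its change of 4.69 (SE 0.47) became 2.08 with 5 CPM added. AKR1C1, AKR1C2 and AKR1C3 are close paralogs, so reads may be shared among them.

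Genes named in advance for the pathway moved as follows. NQO1 (chromosome 16, 69706996 to 69726951), a quinone reductase, rose from 504 ± 24.8 CPM by a log2 change of 1.87 (SE 0.10). The subunits of glutamate-cysteine ligase, the first step of glutathione synthesis, rose by 2.39 (SE 0.09) for GCLC and 2.40 (SE 0.09) for GCLM. The cystine transporter SLC7A11 rose by 1.65 (SE 0.08), thioredoxin reductase TXNRD1 by 1.90 (SE 0.09) and heme oxygenase HMOX1 by 1.26 (SE 0.25). KEAP1, the adaptor that sends NRF2 to degradation, rose from 187 ± 9.81 to 311 ± 14.5 CPM, or 0.73 (SE 0.06). The NRF2 gene itself, NFE2L2, went from 185 ± 5.60 to 160 ± 10.7 CPM, a change of -0.21 (SE 0.06) with adjusted p = 0.017. This call was lost under TMM and median-ratio scaling, where the change was -0.10 and -0.11, and with DMSO library A (adjusted p = 0.12) or KI696 library A (adjusted p = 0.16) left out. It was also lost with no variance trend (adjusted p = 0.074) and with the mean of the lung lineage list as a covariate, where the change was larger at -0.28 (adjusted p = 0.051).

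**Figure D2:**
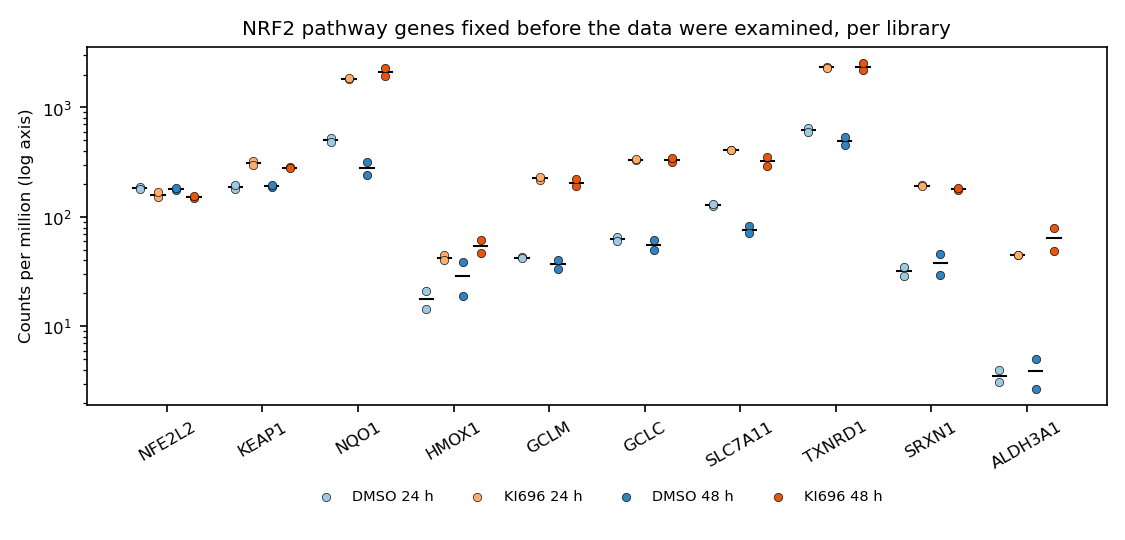
CPM on a log axis of the NRF2 pathway genes named in advance, with 1 point per library and bars at the group means. NQO1 rose from 504 to 1838 CPM at 24 h and from 282 to 2106 CPM at 48 h, and NFE2L2 stayed between group means of 152 and 185 CPM.

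Among the lists of redox and detoxification genes at 24 h, 31 of 34 NRF2 core targets rose and 1 fell (adjusted p = 4.2e-26, and adjusted p = 0.18 with an estimated correlation). UGDH, which makes the sugar donor for glucuronidation, rose by 1.61 (SE 0.06). Of 18 genes of NADPH production and the pentose phosphate pathway, 12 rose and 5 fell (adjusted p = 1.7e-04, and adjusted p = 0.18 with an estimated correlation), with PGD at 1.71 (SE 0.07). Of 28 aldehyde, ketone and quinone oxidoreductases and phase II enzymes, 16 rose and 8 fell (adjusted p = 4.2e-05, and adjusted p = 0.22 with an estimated correlation), among them ALDH3A2 at 1.71 (SE 0.07) and PTGR1 at 2.15 (SE 0.10). Of 21 heme and iron genes, 8 rose and 4 fell (adjusted p = 0.0032, and adjusted p = 0.18 with an estimated correlation). The ferritin chains FTL and FTH1, which store iron, rose by 1.47 (SE 0.08) and 1.32 (SE 0.08). Of 8 drug efflux transporters, 5 rose and 1 fell (adjusted p = 0.0072, and adjusted p = 0.19 with an estimated correlation), with ABCC2 at 1.78 (SE 0.27) and the cholesterol exporter ABCA1 at -1.40 (SE 0.12). Of 19 thioredoxin and peroxiredoxin genes, 7 rose and 4 fell (adjusted p = 0.037, and adjusted p = 0.39 with an estimated correlation), with a median of 0.00 and a mean of 0.15. TXN rose by 1.26 (SE 0.08) and PRDX1 by 0.83 (SE 0.05).

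Genes of the proteasome, the heat shock response, amino acid supply and DNA replication also rose at 24 h. Of 31 proteasome subunits, 22 rose and 0 fell (adjusted p = 8.5e-09, and adjusted p = 0.25 with an estimated correlation), with PSMA3 at 0.51 (SE 0.06) and PSMD11 at 0.52 (SE 0.06). Of 19 heat shock genes, 16 rose and 1 fell (adjusted p = 4.6e-10, and adjusted p = 0.064 with an estimated correlation), with HSPA1B at 1.00 (SE 0.05) and FKBP4 at 0.98 (SE 0.06). Of 32 genes of the amino acid response and ATF4, 18 rose and 3 fell (adjusted p = 1.1e-05, and adjusted p = 0.29 with an estimated correlation). The amino acid transporters SLC1A5 and SLC7A5 rose by 1.02 (SE 0.08) and 0.82 (SE 0.07). Of 30 DNA replication genes, 25 rose and 1 fell (adjusted p = 2.2e-11, and adjusted p = 0.19 with an estimated correlation), with MCM10 at 1.07 (SE 0.08) and CDCA7 at 0.82 (SE 0.06). Mitosis genes moved little. Of 30, 9 rose and 3 fell, with a median of 0.10 that was 0.06 without DMSO library B (adjusted p = 0.011, and adjusted p = 0.57 with an estimated correlation). CCNA2 was at 0.45 (SE 0.06) and CDC25C at -0.63 (SE 0.11). Of 24 glycolysis genes, 12 rose and 4 fell (adjusted p = 0.0087, and adjusted p = 0.37 with an estimated correlation), with the lactate transporter SLC16A1 at 0.54 (SE 0.07) and HK2 at 1.03 (SE 0.15). Of 51 cytosolic ribosomal proteins, 11 rose and 2 fell, with a median of 0.09 that became -0.02 under quantile scaling and 0.06 without DMSO library B (adjusted p = 8.2e-04, and adjusted p = 0.39 with an estimated correlation). RPL14 was at 0.28 (SE 0.05).

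Genes of interferon signalling, early growth factor response and the extracellular matrix were lower at 24 h. Of 31 interferon genes, 0 rose and 23 fell (adjusted p = 2.3e-05, and adjusted p = 0.39 with an estimated correlation), with STAT2 at -1.12 (SE 0.13) and BST2 at -2.16 (SE 0.29). Of the 31, 6 were among the 247 genes that differed between the libraries of 48 h. The mean of the list was 4.20 (A) and 3.61 (B) log2 CPM in DMSO and 3.23 and 2.38 in KI696 at 48 h, and the median change at 24 h was -1.11, or -0.26 with the mean of the lung lineage list of each library as a covariate. Of 15 NF-kB targets and cytokines, 1 rose and 10 fell (adjusted p = 0.02, and adjusted p = 0.19 with an estimated correlation). PTGS2, the inducible cyclooxygenase, fell from 348 ± 9.33 to 197 ± 0.487 CPM, while the cytokine CSF1 rose by 1.55 (SE 0.16). Of 25 immediate early genes, 2 rose and 16 fell (adjusted p = 0.0039, and adjusted p = 0.28 with an estimated correlation), with the phosphatase DUSP6 at -0.99 (SE 0.07) and IER3 at -1.08 (SE 0.07). Of 22 mesenchymal and matrix genes, 3 rose and 14 fell (adjusted p = 0.0044, and adjusted p = 0.18 with an estimated correlation), with SPARC at -0.95 (SE 0.06) and the transcription factor SNAI2 at 1.43 (SE 0.11). Of 24 p53 targets and cell cycle inhibitors, 1 rose and 16 fell (adjusted p = 0.0052, and adjusted p = 0.19 with an estimated correlation), with CDKN1A at -1.76 (SE 0.14) and TP53INP1 at -2.47 (SE 0.34). Of 24 cholesterol synthesis and SREBP genes, 1 rose and 15 fell (adjusted p = 0.0018, and adjusted p = 0.31 with an estimated correlation), with TM7SF2 at -2.42 (SE 0.17). Of 20 genes of the unfolded protein response, 0 rose and 12 fell (adjusted p = 0.023, and adjusted p = 0.19 with an estimated correlation), with CALR at -0.35 (SE 0.05). Of 26 lysosome and autophagy genes, 4 rose and 16 fell (adjusted p = 0.046, and adjusted p = 0.2 with an estimated correlation), with the protease CTSB at -0.70 (SE 0.07) and the autophagy receptor SQSTM1 at 1.18 (SE 0.06). Of 14 replication-dependent histones, whose mRNAs mostly lack the poly(A) tail used for capture, 0 rose and 7 fell (adjusted p = 0.023, and adjusted p = 0.2 with an estimated correlation), with HIST1H2AC at -1.82 (SE 0.22).

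Epithelial and lung lineage genes were also lower at 24 h, along with the library pattern described above. All 21 tested epithelial genes fell (adjusted p = 6.7e-07, and adjusted p = 0.29 with an estimated correlation), with a median of -2.75, and 13 of them were among the 247 genes that differed between the libraries of 48 h. KRT8, a keratin, fell from 715 ± 69.1 to 245 ± 12.8 CPM and CLDN1, a tight junction gene, changed by -1.12 (SE 0.11). Of 8 lung alveolar and airway lineage genes, 0 rose and 7 fell (adjusted p = 0.027, and adjusted p = 0.39 with an estimated correlation), and 4 of the 8 were among the 247. The lineage factor NKX2-1 fell from 24.2 ± 6.78 CPM with a log2 change of -3.89 (SE 0.82). Of 7 tested markers of fibroblasts and endothelium, 0 rose and 7 fell (adjusted p = 4.6e-04, and adjusted p = 0.19 with an estimated correlation), with PDGFRB at -1.70 (SE 0.10) and COL1A1 at -1.80 (SE 0.23). Of 6 leukocyte markers, 0 rose and 3 fell (adjusted p = 0.12). Of the 10 largest decreases, 9 were among the 247: GPR110, NAPSA, CDH1, ARHGDIB, TMEM30B, STEAP4, ST14, SCEL and FAM83A, from -4.56 to -4.27. CDH1, the gene of E-cadherin, fell from 49.2 ± 16.3 to 2.05 ± 1.34 CPM, or -4.53 (SE 0.74). Without KI696 library A of 24 h the calls of GPR110 (adjusted p = 0.075), NAPSA (0.068), SCEL (0.098) and FAM83A (0.068) were lost. With the mean of the lung lineage list of each library as a covariate, CDH1 was at -1.56 and still called, while the calls of the other 8 of these 9 were lost. NAPSA is itself a member of that list. The covariate follows treatment at 24 h, so its use also widens the error there.

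6 lists did not pass as sets at 24 h, besides the leukocyte markers. Of 28 genes of glutathione synthesis and use, 10 rose and 12 fell (adjusted p = 0.11). Their median was -0.13 and their mean 0.09, and glutathione reductase, GSR, rose by 2.13 (SE 0.09). Of 17 regulators of the KEAP1-NRF2 pathway, 6 rose and 7 fell (adjusted p = 0.51), with a median of -0.17 and the test pointing up, and MAFG, a binding partner of NRF2, at 1.06 (SE 0.07). Of 23 targets of hypoxia-inducible factors, 3 rose and 8 fell (adjusted p = 0.6), with CA12 at 1.66 (SE 0.14). Of 37 complex I subunits, 3 rose and 9 fell (adjusted p = 0.97). Of 30 genes of the tricarboxylic acid cycle and malate-aspartate shuttle, 5 rose and 8 fell (adjusted p = 0.66), with a median of -0.01 and the test pointing up. Of 15 fatty acid synthesis genes, 6 rose and 7 fell (adjusted p = 0.45), with a median of 0.02 and a mean of -0.07. Adjusted over the list alone, the counts were 8 higher and 4 lower for thioredoxin genes, 2 higher and 0 lower for ribosomal proteins, 3 higher and 15 lower for the matrix list, 0 higher and 24 lower for interferon, 1 higher and 11 lower for NF-kB, 4 higher and 18 lower for lysosome, 0 higher and 8 lower for histones and 2 higher and 5 lower for complex I subunits, and the same for the others.

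By limma, 6422 of 13213 tested genes differed at 24 h, 2388 higher and 4034 lower with KI696, and 170 and 1285 of these changed by 1 log2 unit or more. With the mean of the lung lineage list as a covariate 3399 differed, 1241 higher and 2158 lower. At 24 h this mean itself follows treatment, at 3.11 and 3.35 in DMSO and 0.36 and 0.50 in KI696. Its slope rests mostly on the libraries A and B of 48 h, and its use widens the error at 24 h. A call lost with it at 24 h may thus reflect that wider error. The balance of directions depended on scaling. With the deposited scaling 37.2% of called genes were higher and the median change of all tested genes was -0.12, against 51.9% and -0.01 under TMM, 50.5% and -0.02 under median-ratio scaling, and 51.7% and 0.04 under quantile scaling. The list tests compare members with all other tested genes, so they are relative to this shift. Under quantile scaling, the call was lost for thioredoxin (adjusted p = 0.19), glycolysis (0.49), mitosis (0.4), ribosomal proteins (0.11) and histones (0.11). Under TMM, it was lost for the unfolded protein response (adjusted p = 0.12) and lysosome (0.095). Under median-ratio scaling, it was lost for the unfolded protein response (adjusted p = 0.086) and lysosome (0.081). With a filter of 5 CPM, it was lost for thioredoxin (adjusted p = 0.068) and lung lineage genes (0.065). With no variance trend, it was lost for thioredoxin (adjusted p = 0.075), the unfolded protein response (0.051), lysosome (0.072) and lung lineage genes (0.054). In a fit of 24 h alone, it was lost for lysosome (adjusted p = 0.072). Without DMSO 24 h A, it was lost for lysosome (adjusted p = 0.053). Without DMSO 24 h B, it was lost for lysosome (adjusted p = 0.054). Without DMSO 48 h A, it was lost for lysosome (adjusted p = 0.0501). Without KI696 24 h A, it was lost for thioredoxin (adjusted p = 0.055) and lysosome (0.067). Without KI696 24 h B, it was lost for mitosis (adjusted p = 0.061). Without KI696 48 h A, it was lost for lysosome (adjusted p = 0.06). Without KI696 48 h B, it was lost for lysosome (adjusted p = 0.06). With voom, it was lost for lung lineage genes (adjusted p = 0.051). With the lung lineage covariate, it was lost for glycolysis (adjusted p = 0.084), interferon (0.2), lysosome (0.12) and histones (0.072). Without both libraries A of 48 h, it was lost for lysosome (adjusted p = 0.07). By fry, it was lost for mitosis (adjusted p = 0.22), ribosomal proteins (0.055) and lung lineage genes (0.056). For the lung lineage list the covariate decides nothing, here and in the other comparisons, because it is the mean of that list.

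**Figure D3:**
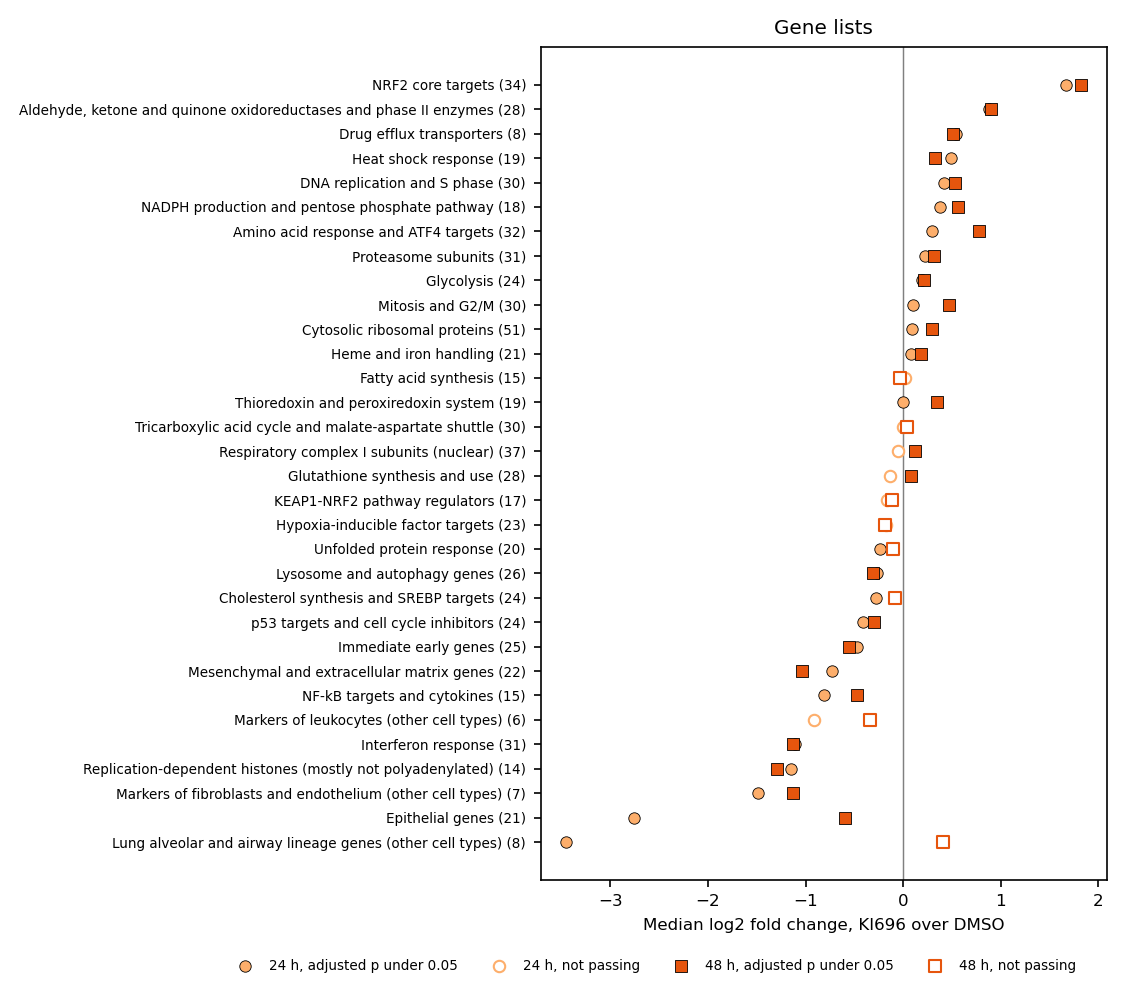
Median log2 change with KI696 of each tested gene list at 24 and 48 h, with 1 marker per time. NRF2 core targets stood at 1.67 and 1.83 and interferon genes at -1.11 and -1.13. Ribosomal proteins stood at 0.09 and 0.30, the first of which was -0.02 under quantile scaling, and lung lineage genes at -3.45 and 0.41.

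At 48 h the NRF2 response was present with a similar set of leading genes. AKR1C2 rose from 5.15 ± 4.36 to 106 ± 19.1 CPM, a log2 change of 4.58 (SE 0.39) with adjusted p = 1.1e-06. The next increases were LOC344887 at 4.47 (SE 0.47), or 1.82 with 5 CPM added, AKR1B10 at 4.04 (SE 0.42), ALDH3A1 (from 3.89 ± 1.68 to 64.2 ± 21.6 CPM) at 3.98 (SE 0.26) and OSGIN1. They were followed by F2RL2, TRIM54, TRIM16L, the complexin gene CPLX3 and the secreted ligand WNT5A, which rose from 8.33 ± 0.828 to 65.3 ± 5.55 CPM, or 2.94 (SE 0.14). NQO1 rose from 282 ± 53.9 to 2106 ± 237 CPM, or 2.91 (SE 0.10). GCLC rose by 2.57 (SE 0.09), GCLM by 2.47 (SE 0.09), SLC7A11 by 2.07 (SE 0.08), TXNRD1 by 2.25 (SE 0.09) and SRXN1 by 2.28 (SE 0.15). KEAP1 rose by 0.57 (SE 0.06) and NFE2L2 changed by -0.26 (SE 0.06) with adjusted p = 0.005. HMOX1 rose by 0.98 (SE 0.25), but by 0.48 without DMSO library B (adjusted p = 0.064) and by 1.48 without DMSO library A.

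Among the largest decreases at 48 h, PCK1, the enzyme that commits carbon to glucose synthesis, changed by -3.16 (SE 0.44). The urea transporter SLC14A1 changed by -3.05 (SE 0.21), the complement gene C7 by -3.24 (SE 0.27), the adhesion gene CEACAM1 by -3.21 (SE 0.20) and the integrin ITGA10 by -3.05 (SE 0.27). BDKRB2, a bradykinin receptor, changed by -2.92 (SE 0.40) and STMN2 by -2.89 (SE 0.22). The death ligand TNFSF10 changed by -3.26 (SE 0.61), and by -1.94 without KI696 library B, still called. Of the 10 largest decreases, 1 was among the 247 that differed between the libraries of 48 h. The choice of the 247 works against the condition that treated and DMSO libraries do not overlap, so a low count is no finding.

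The redox and detoxification lists at 48 h gave the following counts. Of 34 NRF2 core targets, 33 rose and 1 fell (adjusted p = 5.9e-23, and adjusted p = 0.19 with an estimated correlation), among them FTL, from 1329 ± 177 to 5990 ± 345 CPM. Of 18 genes of NADPH production, 12 rose and 5 fell (adjusted p = 1.2e-04, and adjusted p = 0.18 with an estimated correlation), with TKT at 1.62 (SE 0.06) and the malic enzyme ME1 at 2.29 (SE 0.10). Of 28 aldehyde, ketone and quinone oxidoreductases and phase II enzymes, 17 rose and 4 fell (adjusted p = 1.8e-05, and adjusted p = 0.21 with an estimated correlation), with UGDH at 1.65 (SE 0.06) and ALDH3A2 at 1.81 (SE 0.07). Of 21 heme and iron genes, 10 rose and 3 fell (adjusted p = 0.0067, and adjusted p = 0.19 with an estimated correlation), with ferrochelatase FECH at 1.53 (SE 0.08) and the transferrin receptor TFRC at 1.11 (SE 0.06). Of 19 thioredoxin and peroxiredoxin genes, 10 rose and 5 fell (adjusted p = 0.0087, and adjusted p = 0.34 with an estimated correlation), with a median of 0.34 that was 0.17 without DMSO library B. Of 28 glutathione genes, 11 rose and 9 fell (adjusted p = 0.047, and adjusted p = 0.2 with an estimated correlation), with GSR at 2.20 (SE 0.09). Of 8 efflux transporters, 6 rose and 2 fell (adjusted p = 0.047, and adjusted p = 0.21 with an estimated correlation), with ABCC3 at 1.05 (SE 0.11) and ABCA1 at -1.57 (SE 0.12). Of 17 pathway regulators, 5 rose and 6 fell (adjusted p = 0.86), with a median of -0.12 and the test pointing up. SQSTM1 rose by 0.98 (SE 0.06) and MAFG by 1.27 (SE 0.07).

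Several lists of growth and protein synthesis genes were higher with KI696 than with DMSO at 48 h. Of 30 DNA replication genes, 28 rose and 0 fell (adjusted p = 6.7e-13, and adjusted p = 0.19 with an estimated correlation), with CDT1 at 0.78 (SE 0.07). Of 30 mitosis genes, 28 rose and 0 fell (adjusted p = 4.3e-12, and adjusted p = 0.22 with an estimated correlation), with the cyclin CCNA2 at 0.82 (SE 0.06) and the kinase PLK1 at 0.70 (SE 0.06). Of 51 ribosomal proteins, 46 rose and 0 fell (adjusted p = 4.6e-15, and adjusted p = 0.19 with an estimated correlation), with RPL14 at 0.46 (SE 0.05) and RPLP2 at 0.48 (SE 0.06). Of 31 proteasome subunits, 28 rose and 0 fell (adjusted p = 3.3e-10, and adjusted p = 0.21 with an estimated correlation), with PSMD11 at 0.67 (SE 0.06). Of 32 ATF4 and amino acid response genes, 25 rose and 1 fell (adjusted p = 8.3e-13, and adjusted p = 0.19 with an estimated correlation), with asparagine synthetase, ASNS, at 1.55 (SE 0.10) and PSAT1 of serine synthesis at 1.28 (SE 0.08). Of 19 heat shock genes, 14 rose and 2 fell (adjusted p = 6.6e-06, and adjusted p = 0.13 with an estimated correlation), with HSPD1 at 0.84 (SE 0.06). Of 24 glycolysis genes, 13 rose and 4 fell (adjusted p = 0.0055, and adjusted p = 0.34 with an estimated correlation), with ENO1 at 0.52 (SE 0.05) and the glucose transporter SLC2A3 at -0.58 (SE 0.08). Of 37 complex I subunits, 14 rose and 5 fell (adjusted p = 0.042, and adjusted p = 0.53 with an estimated correlation), with NDUFB7 at 0.37 (SE 0.06).

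Interferon, matrix and early response genes were lower at 48 h as well. Of 31 interferon genes, 0 rose and 19 fell (adjusted p = 6.6e-06, and adjusted p = 0.39 with an estimated correlation), with a median of -1.13 that was -0.48 without KI696 library B, and 6 members were among the 247. OASL changed by -2.50 (SE 0.28) and IFIT3 by -2.14 (SE 0.24). Of 22 mesenchymal and matrix genes, 2 rose and 15 fell (adjusted p = 3.4e-05, and adjusted p = 0.13 with an estimated correlation), with fibronectin, FN1, from 2648 ± 140 to 810 ± 153 CPM. Of 25 immediate early genes, 1 rose and 13 fell (adjusted p = 0.0027, and adjusted p = 0.23 with an estimated correlation), with DUSP6 at -0.92 (SE 0.07) and SPRY4 at -0.61 (SE 0.06). Of 15 NF-kB targets, 1 rose and 6 fell (adjusted p = 0.028, and adjusted p = 0.19 with an estimated correlation), with PTGS2 at -1.16 (SE 0.06) and a median of -0.47 that was -0.96 without KI696 library A. Of 24 p53 targets and cell cycle inhibitors, 5 rose and 10 fell (adjusted p = 0.042, and adjusted p = 0.22 with an estimated correlation), with CDKN1A at -1.45 (SE 0.14) and ZMAT3 at -0.77 (SE 0.10). Of 26 lysosome genes, 4 rose and 16 fell (adjusted p = 0.019, and adjusted p = 0.19 with an estimated correlation), with CTSB at -0.93 (SE 0.07). Of 14 histones, 1 rose and 8 fell (adjusted p = 0.0076, and adjusted p = 0.19 with an estimated correlation), with HIST1H2BK at -1.51 (SE 0.13). Of 7 fibroblast and endothelial markers, 0 rose and 5 fell (adjusted p = 0.0053, and adjusted p = 0.21 with an estimated correlation), with PDGFRB at -1.34 (SE 0.10). The epithelial list, on which the library pattern described above bears, had 6 of 21 members lower and 0 higher (adjusted p = 0.042, and adjusted p = 0.61 with an estimated correlation), with KRT8 at -1.12 (SE 0.10). Its median was -0.60, against 0.03 without DMSO library A, -1.25 without DMSO library B, -1.57 without KI696 library A and 0.16 without KI696 library B.

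The lists that did not pass as sets at 48 h were those of the unfolded protein response, cholesterol, fatty acids, hypoxia, the tricarboxylic acid cycle, leukocytes and the lung lineage, besides the pathway regulators. Of 20 genes of the unfolded protein response, 0 rose and 7 fell (adjusted p = 0.28). Of 24 cholesterol genes, 3 rose and 7 fell (adjusted p = 0.28), with TM7SF2 at -2.21 (SE 0.17). Of 15 fatty acid synthesis genes, 6 rose and 5 fell (adjusted p = 0.51), with a median of -0.03 and a mean of 0.12. FASN rose by 0.68 (SE 0.08). Of 23 hypoxia targets, 6 rose and 8 fell (adjusted p = 0.52), with ANGPTL4 at -2.09 (SE 0.27). Of 30 genes of the tricarboxylic acid cycle list, 10 rose and 8 fell (adjusted p = 0.43), with OGDH at -0.61 (SE 0.06) and SDHB at 0.57 (SE 0.07). Of 6 leukocyte markers, 0 rose and 3 fell (adjusted p = 0.43), with LYZ at -2.11 (SE 0.31). Of 8 lung lineage genes, 1 rose and 1 fell (adjusted p = 0.86), with the water channel AQP5 at -2.75 (SE 0.43). Adjusted over the list alone, the counts were 18 higher and 5 lower for aldehyde and phase II enzymes, 11 higher and 4 lower for heme and iron, 15 higher and 2 lower for heat shock genes, 29 higher and 0 lower for mitosis, 14 higher and 5 lower for glycolysis, 49 higher and 0 lower for ribosomal proteins, 0 higher and 22 lower for interferon, 1 higher and 15 lower for immediate early genes, 5 higher and 11 lower for p53, 0 higher and 5 lower for epithelial genes, 3 higher and 6 lower for cholesterol and 5 higher and 7 lower for pathway regulators, and the same for the others.

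By limma, 6445 of 13213 genes differed at 48 h, 2955 higher and 3490 lower, and 259 and 832 of these changed by 1 log2 unit or more. The fit shares the error of each gene over all groups, although libraries of a group differed more at 48 h. Their median absolute log2 difference was 0.138 (DMSO) and 0.127 (KI696) at 48 h, against 0.104 and 0.113 at 24 h. Errors may thus be too small at 48 h and too large at 24 h. Fitted alone, 48 h gave 5565 genes and 24 h gave 7270. The share of higher genes at 48 h was 45.8% with the deposited scaling, 53.5% under TMM, 52.0% under median-ratio and 52.2% under quantile scaling. Under quantile scaling, the call was lost for glutathione (adjusted p = 0.1), efflux transporters (0.072), glycolysis (0.16) and complex I (0.16). Under TMM, it was lost for glutathione (adjusted p = 0.067) and efflux transporters (0.062). Under median-ratio scaling, it was lost for glutathione (adjusted p = 0.071) and efflux transporters (0.06). With 5 CPM added, it was lost for glutathione (adjusted p = 0.0501), efflux transporters (0.053) and epithelial genes (0.055). With a filter of 5 CPM, it was lost for glutathione (adjusted p = 0.072), efflux transporters (0.084), complex I (0.084) and NF-kB targets (0.052). With no variance trend, it was lost for glutathione (adjusted p = 0.096), efflux transporters (0.079) and epithelial genes (0.11). In a fit of 48 h alone, it was lost for glutathione (adjusted p = 0.064), efflux transporters (0.06) and p53 targets (0.051). Without DMSO 48 h A, it was lost for efflux transporters (adjusted p = 0.056), p53 targets (0.059) and epithelial genes (0.45). Without DMSO 48 h B, it was lost for complex I (adjusted p = 0.14). Without KI696 24 h A, it was lost for glutathione (adjusted p = 0.064), efflux transporters (0.056) and epithelial genes (0.052). Without KI696 24 h B, it was lost for glutathione (adjusted p = 0.064), efflux transporters (0.056) and epithelial genes (0.051). Without KI696 48 h A, it was lost for efflux transporters (adjusted p = 0.052) and complex I (0.12). Without KI696 48 h B, it was lost for p53 targets (adjusted p = 0.053), NF-kB targets (0.053) and epithelial genes (0.98). With voom, it was lost for glutathione (adjusted p = 0.059) and efflux transporters (0.059). Without both libraries A of 48 h, it was lost for complex I (adjusted p = 0.083). By fry, it was lost for complex I (adjusted p = 0.1) and epithelial genes (0.27).

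The changes at 24 and 48 h went the same way for most genes. Across the 13213 tested genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.66 and a Spearman correlation of 0.79, and the 2 comparisons share no library. Pearson's value was 0.42 without KI696 library B of 48 h. Of the 8193 genes called at either time, 93.1% had the same sign at both. At both times 2012 genes were called higher, against 534 if calls were independent, and 2635 lower, against 1066, while 27 were called in opposite directions. Both comparisons use the same error estimate for each gene, so the calls are linked and the independent counts are only a loose reference.

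The effect of KI696 differed between 24 and 48 h for 112 genes, 89 with a higher value at 48 h and 23 with a lower. NQO1 was among them, with a difference of 1.04 (SE 0.15) and adjusted p = 0.0097, as were FTL at 0.70 (SE 0.11) and TKT at 0.55 (SE 0.08). NQO1 fell in DMSO from 521 and 486 CPM at 24 h to 320 and 244 at 48 h. With KI696 it went from 1824 and 1852 to 1939 and 2273 CPM, so the difference includes the fall in DMSO. The largest positive differences were SAMD12 at 2.80 (SE 0.39), TSC22D3, a glucocorticoid-induced leucine zipper gene, at 1.90 (SE 0.36), TMEM156 at 1.83 (SE 0.20), RIMS3 at 1.79 (SE 0.26) and ARHGEF16 at 1.54 (SE 0.26). Each of these 5 was lower with KI696 at 24 h, and RIMS3 and ARHGEF16 were higher at 48 h, at 1.12 (SE 0.18) and 0.71 (SE 0.18). The largest negative differences were IGFBP7 at -1.39 (SE 0.22), LRRC17 at -1.38 (SE 0.28), HIST1H2BK at -1.20 (SE 0.18), the lipoprotein gene APOE at -1.11 (SE 0.17) and LTBP2 at -0.90 (SE 0.12).

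As sets, mitosis genes had higher effects at 48 h, with 10 of 30 higher, 0 lower and a median difference of 0.36 (adjusted p = 3.3e-19, and adjusted p = 0.31 with an estimated correlation). Of 32 ATF4 and amino acid response genes, 7 were higher and 0 lower (adjusted p = 7.5e-15, and adjusted p = 0.31 with an estimated correlation), with DDIT4 at 1.36 (SE 0.12) and ASNS at 1.10 (SE 0.14). Of 51 ribosomal proteins, 1 was higher and 0 lower, with a median of 0.23 (adjusted p = 4.9e-20, and adjusted p = 0.31 with an estimated correlation). Positive medians also passed for epithelial genes at 2.19 (adjusted p = 1.1e-08, and adjusted p = 0.39 with an estimated correlation) and lung lineage genes at 3.44 (adjusted p = 0.0021, and adjusted p = 0.4 with an estimated correlation). Both lists had 0 members called, 13 of the 21 and 4 of the 8 genes were among the 247, and the epithelial median was 0.18 with the lung lineage covariate. Without KI696 48 h A the medians were 0.98 and 1.84, and the epithelial one was 1.34 without DMSO 48 h B. Smaller positive medians passed for NRF2 core targets (0.17, adjusted p = 0.014, and adjusted p = 0.64 with an estimated correlation), NADPH production (0.14, adjusted p = 0.014, and adjusted p = 0.31 with an estimated correlation), complex I (0.14, adjusted p = 0.0021, and adjusted p = 0.48 with an estimated correlation), cholesterol (0.20, adjusted p = 0.0021, and adjusted p = 0.45 with an estimated correlation) and DNA replication (0.12, adjusted p = 0.022, and adjusted p = 0.64 with an estimated correlation). Of these, 3, 3, 0, 1 and 2 members were called higher and 0, 0, 0, 0 and 0 lower, in that order. The NRF2 core median was 0.40 without DMSO 48 h A and 0.06 without DMSO 48 h B. The heat shock median was -0.02 without DMSO 48 h A and -0.13 without KI696 24 h B. Negative medians passed for the matrix list (-0.21, adjusted p = 3.9e-05, and adjusted p = 0.24 with an estimated correlation), with FN1 at -0.89 (SE 0.13), and for heat shock genes (-0.07, adjusted p = 9.1e-04, and adjusted p = 0.24 with an estimated correlation). Adjusted over the list alone, 24 mitosis, 20 ATF4, 36 ribosomal, 16 epithelial, 6 lung lineage, 11 NRF2 core, 5 NADPH, 2 complex I, 3 cholesterol and 2 DNA replication genes were higher, and 6 matrix and 3 heat shock genes lower. The other 20 lists did not pass, with adjusted p from 0.065 to 0.83.

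The error of each gene is shared by all groups, and the libraries of a group differed more at 48 h than at 24 h. Leaving out a 24 h library gives the 48 h pairs more weight in that error. A call lost in this way need not rest on the library left out. The count of 112 moved widely as single libraries were left out. It was 5 and 3 without DMSO library A or B of 24 h, 2 and 1 without KI696 library A or B of 24 h, 503 and 80 without DMSO library A or B of 48 h, and 119 and 530 without KI696 library A or B of 48 h. It was 0 without a variance trend, where 1681 genes had an unadjusted p under 0.05, against 2113 with the trend. The 10 genes with the largest differences each lost their call without either KI696 library of 24 h and with no variance trend, 9 without DMSO 24 h A and 9 without DMSO 24 h B. Under TMM, the call was lost for DNA replication (adjusted p = 0.093). Under median-ratio scaling, it was lost for DNA replication (adjusted p = 0.084). With no variance trend, it was lost for NRF2 core targets (adjusted p = 0.13), NADPH production (0.096) and DNA replication (0.096). Without DMSO 24 h A, it was lost for DNA replication (adjusted p = 0.061). Without DMSO 48 h B, it was lost for NRF2 core targets (adjusted p = 0.8) and DNA replication (0.54). Without KI696 24 h A, it was lost for DNA replication (adjusted p = 0.07). Without KI696 24 h B, it was lost for NADPH production (adjusted p = 0.066) and complex I (0.066). Without KI696 48 h B, it was lost for NRF2 core targets (adjusted p = 0.088), NADPH production (0.088) and DNA replication (0.15). With the lung lineage covariate, it was lost for NRF2 core targets (adjusted p = 0.1), complex I (0.16), DNA replication (0.11) and epithelial genes (0.94). Without both libraries A of 48 h, it was lost for cholesterol (adjusted p = 0.2). By fry, it was lost for NRF2 core targets (adjusted p = 0.26), ATF4 targets (0.052), complex I (0.17), cholesterol (0.13), DNA replication (0.22), mitosis (0.052), epithelial genes (0.23) and lung lineage genes (0.23).

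In the vehicle cultures, mitosis genes were lower and several lipid and interferon genes higher at 48 h than at 24 h. Of 30 mitosis genes, 0 rose and 29 fell, with a median of -0.52 (adjusted p = 3.4e-33, and adjusted p = 0.3 with an estimated correlation). KIF20A changed by -0.74 (SE 0.07) and CCNA2 by -0.65 (SE 0.06). FABP4, a fatty acid carrier, rose from 461 ± 40.7 to 1581 ± 134 CPM, a log2 change of 1.78 (SE 0.11) with adjusted p = 1.3e-06. The other largest increases were the neurotrophin receptor NTRK2 at 1.89 (SE 0.25), TFF2 at 1.85 (SE 0.27), CEACAM1 at 1.71 (SE 0.20) and ANGPTL4 at 1.61 (SE 0.27). The largest decreases were SLC34A2 at -3.75 (SE 0.89), KRT4 at -3.40 (SE 0.93), STEAP4 at -3.14 (SE 0.92), ARHGDIB at -3.05 (SE 0.82) and MAL2 at -2.49 (SE 0.69). Each of these 5 decreases lost its call without any of DMSO 24 h A or B, DMSO 48 h B and KI696 24 h A or B (adjusted p up to 0.26), and STEAP4 was at -1.93 without DMSO 48 h B. All but KRT4 were among the 247 genes that differed between the libraries of 48 h. With the lung lineage covariate none of the 5 was called, at -0.94, -0.61, -0.29, -0.37 and -0.28 in the order given.

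Interferon genes had 8 of 31 higher and 0 lower in the vehicle cultures at 48 h (adjusted p = 1.0e-05, and adjusted p = 0.52 with an estimated correlation), with IFIT3 at 1.32 (SE 0.24). Immediate early genes had 8 higher and 1 lower (adjusted p = 4.3e-04, and adjusted p = 0.35 with an estimated correlation), with JUND at 0.72 (SE 0.09). ATF4 and amino acid response genes had 1 higher and 10 lower (adjusted p = 5.1e-06, and adjusted p = 0.43 with an estimated correlation), with DDIT4 at -0.81 (SE 0.08). NRF2 core targets had 2 higher and 8 lower (adjusted p = 0.0018, and adjusted p = 0.52 with an estimated correlation), with NQO1 at -0.85 (SE 0.10) and SLC7A11 at -0.76 (SE 0.08). The matrix list had 4 higher and 1 lower (adjusted p = 0.012, and adjusted p = 0.3 with an estimated correlation), with FN1 at 0.83 (SE 0.09). Fatty acid synthesis had 5 higher and 1 lower (adjusted p = 0.012, and adjusted p = 0.3 with an estimated correlation), with the desaturase SCD at 0.43 (SE 0.06). Lung lineage genes had 0 higher and 3 lower (adjusted p = 0.0054, and adjusted p = 0.43 with an estimated correlation) and epithelial genes 1 and 0 (adjusted p = 0.011, and adjusted p = 0.52 with an estimated correlation) with 4 of the 8 and 13 of the 21 genes among the 247. The epithelial median was -0.49, against -1.23 without DMSO 48 h A, -0.26 without DMSO 48 h B and 0.55 with the covariate (adjusted p = 9.2e-04). The interferon median was 0.45, against 0.21 without DMSO 48 h A and 0.84 without DMSO 48 h B. Lists with smaller medians that passed were DNA replication (-0.10, adjusted p = 0.012, and adjusted p = 0.52 with an estimated correlation), heat shock (-0.10, adjusted p = 0.0054, and adjusted p = 0.3 with an estimated correlation), ribosomal proteins (0.04, adjusted p = 0.011, and adjusted p = 0.52 with an estimated correlation), the unfolded protein response (0.09, adjusted p = 0.029, and adjusted p = 0.33 with an estimated correlation), proteasome (-0.07, adjusted p = 0.033, and adjusted p = 0.58 with an estimated correlation) and cholesterol (0.09, adjusted p = 0.043, and adjusted p = 0.52 with an estimated correlation). Adjusted over the list alone, the higher and lower counts were 0 and 30 for mitosis, 8 and 0 for interferon, 10 and 1 for immediate early genes, 2 and 11 for ATF4, 2 and 8 for NRF2 core targets, 8 and 2 for the matrix list, 7 and 2 for fatty acid synthesis, 1 and 6 for the lung lineage and 1 and 0 for epithelial genes. In the lists with smaller medians, the counts over all genes were 0 and 2 for DNA replication, 0 and 4 for heat shock, 1 and 0 for ribosomal proteins, 2 and 0 for the unfolded protein response, 0 and 1 for proteasome and 2 and 0 for cholesterol. The other 17 lists did not pass, with adjusted p from 0.065 to 0.93.

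By limma, 1274 genes differed between the vehicle groups, 699 higher and 575 lower at 48 h. The count was 316 and 448 without DMSO library A or B of 24 h, 1408 and 782 without DMSO library A or B of 48 h, 826 and 828 without KI696 library A or B of 24 h, and 1646 and 1605 without KI696 library A or B of 48 h. It was 153 without a variance trend. Under quantile scaling, the call was lost for the unfolded protein response (adjusted p = 0.075), cholesterol (0.075), the matrix list (0.072) and ribosomal proteins (0.9). Under TMM, it was lost for proteasome (adjusted p = 0.053). Under median-ratio scaling, it was lost for proteasome (adjusted p = 0.0503). With a filter of 5 CPM, it was lost for cholesterol (adjusted p = 0.053). With no variance trend, it was lost for proteasome (adjusted p = 0.059), the unfolded protein response (0.059), cholesterol (0.1), the matrix list (0.059) and epithelial genes (0.059). Without DMSO 24 h A, it was lost for proteasome (adjusted p = 0.2), cholesterol (0.12) and epithelial genes (0.095). Without DMSO 24 h B, it was lost for the unfolded protein response (adjusted p = 0.075) and ribosomal proteins (0.14). Without DMSO 48 h A, it was lost for proteasome (adjusted p = 0.15), the unfolded protein response (0.051) and fatty acid synthesis (0.077). Without DMSO 48 h B, it was lost for NRF2 core targets (adjusted p = 0.44), the unfolded protein response (0.051), cholesterol (0.22), DNA replication (0.47), epithelial genes (0.48) and lung lineage genes (0.051). With the lung lineage covariate, it was lost for the unfolded protein response (adjusted p = 0.076) and DNA replication (0.07). Without both libraries A of 48 h, it was lost for proteasome (adjusted p = 0.18), the unfolded protein response (0.054) and fatty acid synthesis (0.08). By fry, it was lost for NRF2 core targets (adjusted p = 0.2), proteasome (0.21), ATF4 targets (0.079), cholesterol (0.2), DNA replication (0.2), interferon (0.2), immediate early genes (0.057), epithelial genes (0.55), ribosomal proteins (0.2) and lung lineage genes (0.2).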

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

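The tests on exchanged labels, on an effect of KI696 alone for the lung lineage pattern, and the last of those on PPAR targets were chosen only after the result was seen. So were the definitions of the 247 genes and of the PPAR list, and these patterns remain hypotheses. The test of KI696 alone was changed after its values were seen: against a first bound of 1, neither the DMSO pair nor the mean of both pairs passed by 2 SE, and the bound now is the largest difference within a group of 24 h. The scaling test of mitosis genes was limited to quantile scaling, and the p values of the PPAR list were adjusted over all fixed and added lists in place of the added ones alone, after the values were seen. The bound of the PPAR test on RNA of other cells was changed as well, to count markers of other cells, since leaving out the libraries A did not remove these.

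The KI696 effect differed between 48 and 24 h in a direct test for 112 genes. Among the named ones the difference was 2.80 for SAMD12, 1.90 for TSC22D3, 1.83 for TMEM156, 1.79 for RIMS3, 1.54 for ARHGEF16, -1.39 for IGFBP7, -1.38 for LRRC17, -1.20 for HIST1H2BK, -1.11 for APOE and -0.90 for LTBP2. Each of these 10 calls was lost without either KI696 library of 24 h and with no variance trend, 9 without DMSO 24 h A and 9 without DMSO 24 h B. The count of 112 fell to 2 and 1 without KI696 24 h A or B, to 5 and 3 without DMSO 24 h A or B, and to 0 with no variance trend. Calls lost without a 24 h library need not rest on that library, because the error is shared by all groups and the 48 h pairs differed more. The difference was 1.04 for NQO1, 0.55 for TKT, 0.70 for FTL, 0.73 for SLC7A5, 1.10 for ASNS, 0.60 for INSIG1, 0.95 for CDC25C, 0.51 for CDT1, 0.51 for PTTG1 and -0.89 for FN1. By list, the median difference was 0.17 for NRF2 core targets, 0.14 for NADPH production, 0.40 for ATF4, -0.068 for heat shock, 0.14 for complex I, 0.20 for cholesterol, 0.12 for DNA replication, 0.36 for mitosis, -0.21 for the matrix list, 2.19 for epithelial genes, 0.23 for ribosomal proteins and 3.44 for the lung lineage.

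The lung lineage list was high in both DMSO libraries of 24 h and in library A of each 48 h group, and low in the other 4 libraries, and exchanged labels of a DMSO and a KI696 library are argued against, because the lowest KI696 library exceeded the highest DMSO library by 1.70 log2 units over the NRF2 core list. The test of KI696 alone adds no separate evidence, because the difference between libraries A and B is the pattern that prompted it. Library A exceeded library B of the same treatment by 2.06 (SE 0.54 over 8 genes) across both 48 h groups, at 1.30 (SE 0.41) in DMSO and 2.82 (SE 0.69) in KI696. Within a group of 24 h the libraries differed by at most 0.23. The SE is over genes that may move together, and not over libraries. A difference between libraries of the same treatment is not set by treatment alone, but the 24 h change is not addressed. RNA from a single other source stays open, since chi-square per degree of freedom of the extra reads was 7.41, against a largest value of 4.88 within a group and a bound at 2 times that. RNA of other cells or samples from more than 1 source may have contributed but cannot be told apart from a state of the cells. In all, 16 pairs of the genes were neighbours on a chromosome, above the 1 to 10 of random lists (median 5, 0 of 10000 as high). Yet 8 pairs are of like-named gene families and the other 8 reach the top of the random range of 1 to 8. This split by name was added after seeing the count. A single source could give neighbours as well, so the count cannot bear on the number of sources. On chromosome 21, HSPA13, NRIP1 and USP25 had 3 to 7 reads in the KI696 libraries of 24 h and 56 to 153 in the DMSO libraries of 24 h, while BTG3 lay at 20.5 to 23.0 CPM and C21orf91 at 12.5 to 16.1 CPM in all 8, but CXADR, between USP25 and BTG3, ranged from 34.8 to 85.8 CPM with the highest value in DMSO 48 h B, USP25 was not among the 247, and the segment was picked after seeing the values, so it decides nothing.

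Mitosis genes fell with time in DMSO, with a median of -0.52, and less with KI696, with a median of -0.13, 0 higher and 10 lower. Library scaling as the whole cause is argued against, because under quantile scaling the list stayed above the median of all genes by 0.37 in the difference of effects, a measure that TMM and median-ratio scaling, with 1 factor per library, could not change. The libraries A of 48 h were not needed for the difference, with a median of 0.48 without them and 0.36 with all 8 libraries. This leaves 1 library in each 48 h group, so the spread between libraries cannot be judged there. Over the list, the libraries B (6.79 log2 CPM in DMSO and 7.36 in KI696) also lay further apart than the libraries A (6.95 and 7.31), which favours a larger estimate. An effect of KI696 on proliferation in ageing cultures stays open as a hypothesis, and no biological explanation was tested, since cell numbers are not given.

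Target genes of PPAR, the nuclear receptors of fatty acid metabolism, were lower with KI696 in a list assembled after seeing some of its genes, so the direction is not independent evidence: of 34 tested, 0 rose and 24 fell at 24 h, and 2 rose and 21 fell at 48 h. For the 48 h change, RNA of other cells in the DMSO libraries cannot be told apart from an effect of KI696: without both libraries A of 48 h the median change was -0.46 (adjusted p = 3.5e-05, and adjusted p = 0.16 with an estimated correlation, 21 lower and 1 higher), but this leaves 1 library per group, and between these the means of the markers of fibroblasts and endothelium (3.75 in DMSO and 2.74 log2 CPM in KI696), of leukocytes (2.14 and 1.65) and of the lung lineage (0.49 and -0.24) were lower with KI696 too. The 24 h change was not tested, since both DMSO libraries are high in lung lineage genes. Lower transcription driven by PPAR is consistent with the 22 members that had neither prompted the list nor stood in a list fixed earlier, whose higher median of the 2 times was -0.33 (adjusted p = 0.0095 at 24 h and 0.0075 at 48 h, adjusted p = 0.14 and 0.14 with an estimated correlation). Members of the fixed lists were taken out of this test after a first value had been seen, and each p was adjusted over 38 lists, the 32 fixed and 6 added.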

How the results depend on the processing

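The alternatives that use the lung lineage covariate, leave out the libraries A of 48 h or the 247 tracking genes, use voom on recovered reads or log2 of CPM plus 1, were chosen after seeing the data. Of 6626 comparisons of 303 gene results with 23 settings, 6436 kept direction and side of the threshold, 181 lost the call, 4 gained it and 5 changed sign. For 49 list results under 24 settings the counts were 1003 of 1127 kept, 121 lost and 3 with a changed sign, and the cause was not tested except where a setting's construction shows it. Most of these genes were named for large changes or small p in the main fit, and the lists are those that passed there. Leaving out a library of the other time cannot alter a log2 change, only its error. That error is shared by all groups, so leaving out a 24 h library moves it toward the wider spread of the 48 h pairs. The counts are therefore no measure of robustness for all genes or lists. With an estimated correlation, which rests on 4 residual degrees of freedom, 0 lists passed in each of the 4 contrasts. With fry 5 passed for the difference of effects and 8 for DMSO over time, against 12 and 15. With a change of at least 1 log2 unit required, the counts were 1455 (24 h), 1091 (48 h), 34 (difference) and 135 (DMSO over time). The difference count of 112 became 190 with 5 CPM added, 65 with no filter and 0 with no variance trend (1681 at an unadjusted p under 0.05), and DMSO over time became 153 with no variance trend. The correlation of fold changes was 0.80 with 5 CPM added. The covariate left 3399 genes at 24 h, where it follows treatment and widens the error. Without both libraries A of 48 h, the difference count was 838 and DMSO over time 2205. With single libraries left out the ranges were 4666 to 6635 genes at 24 h, 5291 to 6166 at 48 h, 1 (without KI696 24 h B) to 530 (without KI696 48 h B) for the difference, 316 to 1646 for DMSO over time, and 0.42 to 0.79 for the correlation. Lists passing ranged from 23 to 25 at 24 h, 21 to 24 at 48 h, 10 to 16 for the difference and 10 to 16 for DMSO over time. Signs changed for AGER at 48 h (0.19 under quantile scaling), GPR110 and NAPSA at 24 h (0.042 and 0.39 with the covariate), SFTPA1 at 48 h (-0.01 without DMSO B, -0.88 without KI696 A, 3.59 without KI696 B), ribosomal proteins at 24 h (-0.023 under quantile scaling), epithelial genes at 48 h (0.16 without KI696 B, -1.57 without KI696 A) and the test direction of lung lineage genes at 24 h (median -0.020 with the covariate, which is that list's mean, so this value is fixed by construction). The planned fits with edgeR and DESeq2 were not run. The deposited unit is log2 and not counts, and limma's voom on the recovered whole reads was run in their place. No paired analysis was possible because the columns carry no replicate number, so the alternatives with a replicate block were not run. Depth limits genes near 0.213 to 0.428 CPM, the level of 3 reads.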

Other observations

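The lists described here were assembled after seeing the data and are not independent evidence of direction. Their p values were adjusted over 38 lists per comparison, the 32 fixed earlier and 6 added ones, and none passed with an estimated correlation. Ribosome biogenesis factors, which make and process ribosomal RNA in the nucleolus, rose at both times. Of 49 tested, 48 rose and 0 fell at 24 h, with a median of 0.68 (adjusted p = 4.6e-30, and adjusted p = 0.13 with an estimated correlation). At 48 h 46 rose and 0 fell, with a median of 0.76 (adjusted p = 1.3e-24, and adjusted p = 0.14 with an estimated correlation). The RNA helicase DDX21 rose by 1.17 (SE 0.06) and 1.13 (SE 0.06), NOP56 by 0.98 (SE 0.07) at 24 h, and nucleophosmin, NPM1, by 0.77 (SE 0.05) at 48 h. Among the 38 members that had not prompted the list, 37 rose at 24 h and 35 at 48 h, and 0 fell at either time. FoxO target genes, many of which restrain growth or promote atrophy and autophagy, were lower. Of 31, 1 rose and 23 fell at 24 h (adjusted p = 5.2e-06, and adjusted p = 0.13 with an estimated correlation), and 1 rose and 20 fell at 48 h (adjusted p = 1.0e-04, and adjusted p = 0.14 with an estimated correlation). YPEL5 changed by -1.56 (SE 0.08) and -1.33 (SE 0.08), the mitophagy kinase PINK1 by -1.38 (SE 0.11) and -1.23 (SE 0.11), and the cell death gene BMF by -1.94 (SE 0.13) and -1.77 (SE 0.13). Of the 17 members that had not prompted this list, 1 rose and 11 fell at 24 h, and 0 rose and 10 fell at 48 h (adjusted p = 0.019 and 0.015, and adjusted p = 0.14 and 0.14 with an estimated correlation). Markers of fibroblasts and endothelium were lower with KI696 at 24 h too, with means of 4.47 and 4.32 log2 CPM in DMSO and 2.48 and 2.80 in KI696. Whether RNA of other cells contributed to the fall of FoxO targets was not tested.

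In the PPAR list, FABP4 changed by -2.27 (SE 0.11) at 24 h and -2.24 (SE 0.11) at 48 h, the pyruvate dehydrogenase kinase PDK4 by -1.80 (SE 0.12) and -0.97 (SE 0.12), and the lipid droplet gene PLIN4 by -1.42 (SE 0.14) and -1.15 (SE 0.14). In the vehicle cultures 14 of 34 members of this list rose between 24 and 48 h and 0 fell (adjusted p = 1.6e-09, and adjusted p = 0.14 with an estimated correlation).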
